A study of Homo sapiens with 4 samples.

How the data were processed

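Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in ME-1 cells. ME-1 is an established human acute myeloid leukaemia line with the inv(16) rearrangement, which joins CBFB to MYH11 and gives the fusion protein CBFβ-SMMHC. Per the labels, cells received the solvent DMSO or AI-10-49, an inhibitor of the binding of CBFβ-SMMHC to RUNX1, at 1 µM for 6 h. The series' design text speaks of independent experiments for each treatment, and each group held 2 libraries. Group and replicate number were taken from the sample titles.

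The deposited data were 4 lists of peaks, 1 per library, on genome build hg19 per the submitters' processing notes. Those notes name cutadapt 1.3, Bowtie2, Picard 1.96, MACS2 2.1.0 and deepTools without saying what each was used for, and peak calling settings were not given in the sources used here. Each deposited peak carried an integer score, a fold enrichment at the summit, and the −log10 of a p-value and of a q-value, all as the authors' peak caller wrote them. The score column was not used further. The lowest deposited −log10 q-value was 1.31, 1.31, 1.30 and 1.31 in DMSO replicates 1 and 2 and AI-10-49 replicates 1 and 2. Fold and −log10 p-value were the authors' own values for a peak within its list. They served to rank and filter peaks within a list and to recover summit reads and background, and the heights and percentiles derived from them are set side by side between libraries as description, without a test.

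Peaks on chromosomes 1 to 22 and X were kept. Rows with the same coordinates and different summits were collapsed into 1 peak with the highest −log10 p-value. The number of reads at a summit was recovered from the deposited fold and −log10 p-value under a Poisson model, as the whole number whose predicted −log10 p-value lay closest, with a tolerance of 0.001. Whole numbers were found for 99.99% of peaks in DMSO replicate 1, and 4 or 5 peaks per library had none. The same step gave the most frequent background level, in reads per base. Total reads per library and the read extension length were not given in the sources used here, so depth was described by these values only.

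Regions were formed by merging peaks of the 4 lists that overlapped by at least 1 bp. A region was called DMSO-only if both DMSO lists and neither AI-10-49 list held a peak there, and AI-10-49-only in the opposite case. Peak strength was the percentile of the −log10 p-value within its list. Group means were compared with two-sided exact permutation tests. Shares of regions were compared with two-sided Fisher's exact tests and with 10000 random region sets matched on strength in 10 strata. Such tests compare these peak lists and not the conditions, because regions are not replicates. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only.

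The MYC domain was the 1 Mb bin of chromosome 8 holding MYC and the 2 bins after it. An excess of DMSO-only or AI-10-49-only regions was tested in every 1 Mb bin with at least 3 regions, by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment and a threshold of 0.05. Bins took the place of genes, as laid down before the data were examined for the case that no annotation of hg19 was given. The regions and bins named are MYC, RUNX1 and CBFB, and, for each kind, the 12 bins with the smallest p-value and the 6 strongest regions. Strength of a region was the lower of its 2 percentiles. Approximate hg19 positions of MYC, RUNX1 and CBFB came from general knowledge, and regions with a midpoint within 100 kb of them were counted as theirs.

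Neither an annotation nor the sequence of hg19 was used here. Tests of promoter against distal regions, of 15 gene lists and of 23 motifs, all laid down before the data were examined, were therefore not made. A trial of the gene lists with approximate gene positions from general knowledge was withdrawn in full, including lists that had passed the threshold in the deposited lists or under alternative settings, because the design called these tests void without an annotation of the build. Protein-coding genes per chromosome were counted from a RefSeq table of GRCh38.p14, of which no coordinate was used, and divided by the position of the last peak on the chromosome.

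Alternatives laid down before the data were examined were a −log10 q-value of at least 5, the strongest 48930 or 24465 peaks of every list, changed regions with a percentile of at least 50 in both lists, 50% reciprocal overlap, summits within 150 bp, matching on strength, pairing by replicate number and leaving out each library. Added after seeing the data were a summit pileup of at least 60 times the library's background, a pileup of at least 5 reads in every list, the comparison of chromosomes, and a simulated loss. For the last, sites found in both groups were taken out of both AI-10-49 lists of equal length until these were shorter by the share seen between the groups, and all lists were brought to the shortest length again (10 draws). Procedures were tested on simulated data. All 200 DMSO-only and 200 AI-10-49-only regions planted in the comparison of DMSO with AI-10-49 were recovered. The simulated lists were copies of the regions found in all libraries, shifted by a few bases. Planted sites were deleted outright from the other group, and no weak or missed peaks were simulated. Full recovery was thus fixed by construction and does not measure sensitivity at weak sites. Of 20 planted bins among 2608, each with at least 10 regions, 82.2% were recovered at a DMSO-only share of 60% and 3.75% at a share of 30%, with 0 false bins on average; recovery of smaller bins was not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.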

Results

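Accessible chromatin of ME-1 leukaemia cells was compared after 6 h with DMSO or with 1 µM AI-10-49, with 2 libraries per treatment. The series asks how inhibition of CBFβ-SMMHC acts on the chromatin of MYC, the gene of a transcription factor that drives cell growth. The peak lists held 67388 and 65132 peaks in DMSO replicates 1 and 2, and 48930 and 53438 in AI-10-49 replicates 1 and 2. The background was 0.0613 and 0.060 reads per base in the DMSO libraries, and 0.0965 and 0.108 in the AI-10-49 libraries. Peaks needed fewer reads in the DMSO lists, where the minimum was 2 reads at the summit, than in the AI-10-49 lists, where it was 3.

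In the deposited lists, peaks were fewer and wider after AI-10-49. The mean was 66260 ± 1595 peaks (SD, n = 2) with DMSO and 51184 ± 3188 (SD, n = 2) with AI-10-49, a difference of -22.8%. Mean peak width was 130.1 ± 3.22 bp with DMSO and 146.5 ± 3.26 bp with AI-10-49 (SD, n = 2 each). Width was compared in the deposited lists only, so whether this difference holds under other settings was not tested. Peaks covered 8921480 and 8326306 bp in the DMSO libraries, and 7056657 and 7953407 bp in the AI-10-49 libraries. The groups did not overlap in either number or length, and the exact permutation p was 0.333 for each, the smallest that 2 against 2 libraries allow. Peaks with 2 reads at the summit occurred in the DMSO lists alone, where they numbered 10239 and 10790, or 15.2% and 16.6% of the lists. With a −log10 q-value of at least 5 the mean difference turned to 1940.5 more peaks with AI-10-49, and the lists then held 33081 and 29635 peaks with DMSO and 31238 and 35359 with AI-10-49. With pileups of at least 60 times the background, which asked for 4 reads in the DMSO and 6 or 7 in the AI-10-49 libraries, the gap stayed, at 44102.5 peaks with DMSO and 30411 with AI-10-49 on average (-31.0%). With at least 5 reads everywhere, which is 81.6 and 83.3 times the background with DMSO and 51.8 and 46.5 times with AI-10-49, it turned, with 36256 and 33177 peaks against 37979 and 42542.

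**Figure D1:**
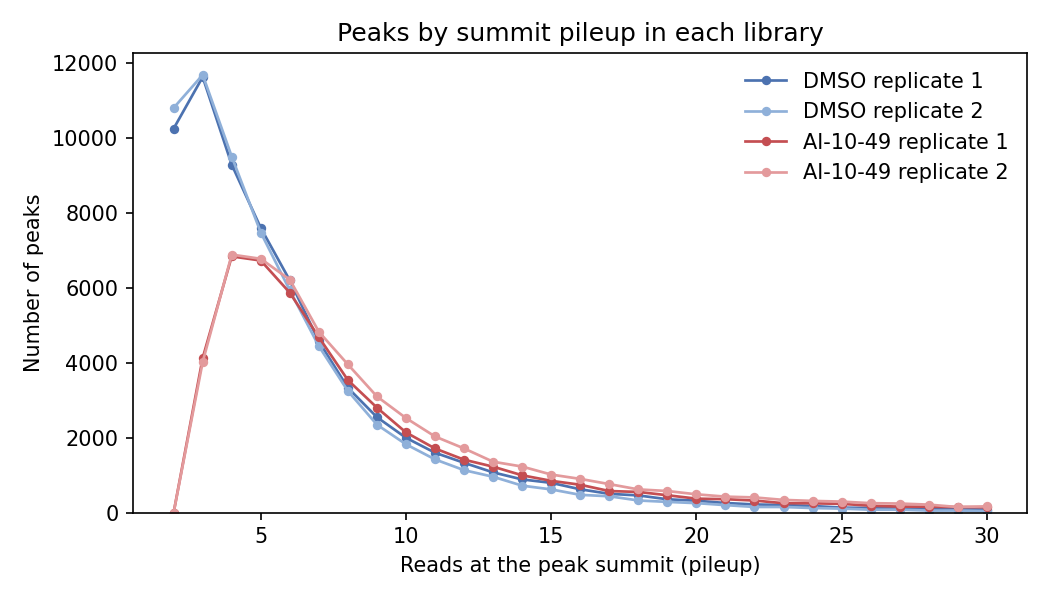
Number of peaks (vertical axis) by reads at the peak summit (horizontal axis, up to 30 reads), with 1 line per library and no error bars. The DMSO lists start at 2 reads, with 10239 and 10790 such peaks, and the AI-10-49 lists start at 3.

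Most strong accessible sites were shared by treated and untreated cells. Of 103230 merged regions, 29042 held a peak in all 4 libraries, which was 70.9% of the 40978 regions found in both DMSO libraries and 78.4% of the 37031 found in both AI-10-49 libraries. A single library alone held 45277 regions. Among DMSO replicate 1 peaks with 10 to 19 reads at the summit, 99.2% overlapped a peak of at least 1 AI-10-49 library, against 16.7% of those with 2 reads. The Jaccard index of covered bases was 0.417 between the DMSO libraries, 0.526 between the AI-10-49 libraries and 0.430 to 0.464 across treatments. In the deposited lists the DMSO pair thus lay below every pair across treatments. With the strongest 48930 peaks of every list it was 0.459, against 0.458 to 0.496 across treatments, and with pileups of at least 60 times the background it was 0.481, against 0.473 to 0.493. With a −log10 q-value of at least 5 it was 0.475 and again below every pair across treatments (0.476 to 0.510).

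In the deposited lists, 4840 regions were DMSO-only and 1985 were AI-10-49-only. These made up 11.8% of the regions in both DMSO libraries and 5.36% of those in both AI-10-49 libraries, and DMSO-only regions were 70.9% of all such regions (95% interval 69.8 to 71.99%). Both kinds were mostly weak sites: the less covered library had a median of 3 reads at DMSO-only and 5 at AI-10-49-only regions, against 6 (DMSO) and 8 (AI-10-49) at regions of all 4 libraries. At least 10 reads in both libraries were found at 4 DMSO-only and 67 AI-10-49-only regions, but 10 reads are 163.1 and 166.7 times the background with DMSO and 103.6 and 92.9 times with AI-10-49. By a percentile of at least 50 in both lists the order was the opposite, with 519 DMSO-only and 147 AI-10-49-only regions. This cut was not equal between groups, as the lists differed in length. Their median peak had 5 reads with DMSO and 7 with AI-10-49, or 81.6 and 83.3 against 72.5 and 65.1 times the background. Pairs that mix treatments alone held 1636 to 2834 regions of any strength, a range that includes the AI-10-49-only number of 1985 and lies below the DMSO-only number of 4840. With a −log10 q-value of at least 5, mixed pairs held 928 to 2089 regions, the DMSO pair 1355 and the AI-10-49 pair 2436. With at least 5 reads these numbers were 953 to 2075, 1025 and 3132. With pileups of at least 60 times the background they were 910 to 1548, 5237 and 689. The direction depended on the lists used. DMSO-only regions were 35.7% with a −log10 q-value of at least 5 and 24.7% with at least 5 reads, but 77.9% among regions with a percentile of at least 50 and 88.4% with pileups of at least 60 times the background. They were 45.2% with the strongest 48930 peaks of every list and 44.6% with the strongest 24465, where equal totals of peaks in both groups draw the share toward balance by construction. Leaving out a library relaxes the presence criterion for its own group and the absence criterion for the other. DMSO-only and AI-10-49-only regions rose to 21981 and 5611 without DMSO replicate 1, and to 7611 and 8502 without AI-10-49 replicate 1. The share was 79.7% and 83.4% without DMSO replicate 1 or 2, and 47.2% and 57.0% without AI-10-49 replicate 1 or 2.

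**Figure D2:**
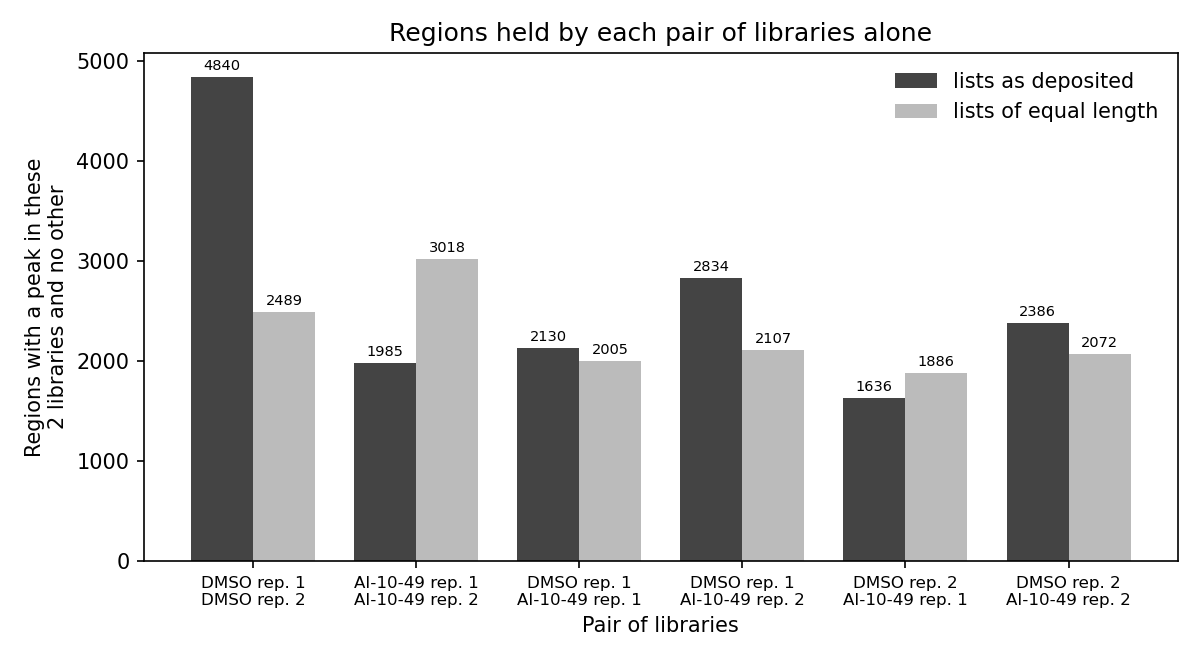
Bars give the number of regions with a peak in the named 2 libraries and in no other, for the deposited lists (dark) and for the strongest 48930 peaks of every list (light); bars are counts without error. At equal length the DMSO pair held 2489 regions and the AI-10-49 pair 3018, and the pairs that mix treatments held 1886 to 2107.

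The strongest DMSO-only region was chr11:105733630–105733748 (hg19), with 10 and 11 reads at the summit in the DMSO libraries. It was followed by chr8:143342183–143342328 with 9 and 8 reads, chr4:167942844–167942949 with 9 and 8, chr10:129554086–129554304 with 7 and 7, chr11:111741768–111741891 with 10 and 9, and chr2:159981278–159981374 with 9 and 10. The strongest AI-10-49-only region was chr6:13574713–13574839, with 21 and 20 reads in the AI-10-49 libraries. Next came chr2:133023160–133023269 with 23 and 32 reads, chr3:126194707–126194952 with 15 and 18, chr1:121478627–121478711 with 11 and 12, chr16:33950153–33950224 with 15 and 19, and chr1:142890942–142891048 with 10 and 9. No filter for repetitive or poorly mappable sequence was applied here, so some of these regions may lie in such sequence. Genes at these positions were not assigned, as no annotation of hg19 was used here.

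The strongest peak within 5 kb of the MYC position, chr8:128747429–128747695, was listed in all 4 libraries. Its summit had 19 and 21 reads with DMSO and 15 and 25 with AI-10-49, which is 310.0 and 350.0 times the library's background with DMSO and 155.4 and 232.3 times with AI-10-49. Its percentile in the list was 88.8 and 94.2 with DMSO and 72.1 and 88.8 with AI-10-49. Heights over the background were lower after AI-10-49 across the genome as well. The median at regions of all 4 libraries was 130.5 and 116.7 times with DMSO and 93.3 and 92.9 times with AI-10-49. Whether the fall at MYC went beyond this was not tested. The nearest other region, chr8:128748112–128748184, was listed in AI-10-49 replicate 2 only, with 9 reads. Close by, chr8:128746312–128746495 was listed in all 4 libraries. Its height was 244.7 and 216.7 times the background with DMSO and 134.7 and 130.1 times with AI-10-49. At chr8:128748269–128748562, also listed in all 4, the heights were 146.8 and 133.3 times with DMSO and 124.4 and 92.9 times with AI-10-49. Within 100 kb of MYC there were 19 regions, of which 6 held a peak in all 4 libraries, 1 was DMSO-only and 0 were AI-10-49-only. That DMSO-only region, chr8:128738089–128738183, had 3 and 2 reads. Over the whole MYC domain, chr8:128000001–131000000, 50 of 180 regions held a peak in all 4 libraries, 9 were DMSO-only and 3 were AI-10-49-only.

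The shares of DMSO-only and of AI-10-49-only regions in the MYC domain did not differ detectably from those elsewhere. DMSO-only regions were 9 of the 71 domain regions found in both DMSO libraries, or 12.7% (95% interval 5.96 to 22.7%), against 11.8% elsewhere (odds ratio 1.08, two-sided Fisher's exact p = 0.853, p = 0.382 against sets matched on strength). AI-10-49-only regions were 3 of 63, or 4.76% (0.993 to 13.3%), against 5.36% elsewhere (odds ratio 0.883, Fisher's exact p = 1). The intervals are wide, so a moderately higher or lower share was not detectable with this number of regions. These tests count only whether a peak was listed. A change in height at a region listed in all 4 libraries does not enter them, so they do not address a partial loss of accessibility. The first bin, which holds MYC, had 5 DMSO-only regions of 22 (22.7%, Fisher's exact p = 0.172) and the second had 4 of 29 (13.8%, Fisher's exact p = 0.771). The third bin, chr8:130000001–131000000, which contains a distal cluster of blood enhancers of MYC, had 0 of 20 (95% interval 0 to 16.8%, Fisher's exact p = 0.159). In that bin, chr8:130593907–130594647 was listed in all libraries with 34 and 23 reads with DMSO and 37 and 35 with AI-10-49, or 554.6 and 383.3 times the background with DMSO and 383.4 and 325.3 times with AI-10-49. By the lower of its 2 percentiles (51.7), the strongest DMSO-only region of the domain was chr8:129027074–129027179, 279.6 kb from the MYC peak. It had 7 and 4 reads. By reads, chr8:128929374–128929496 was higher, with 8 and 6, at a lower percentile of 26.8.

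**Figure D3:**
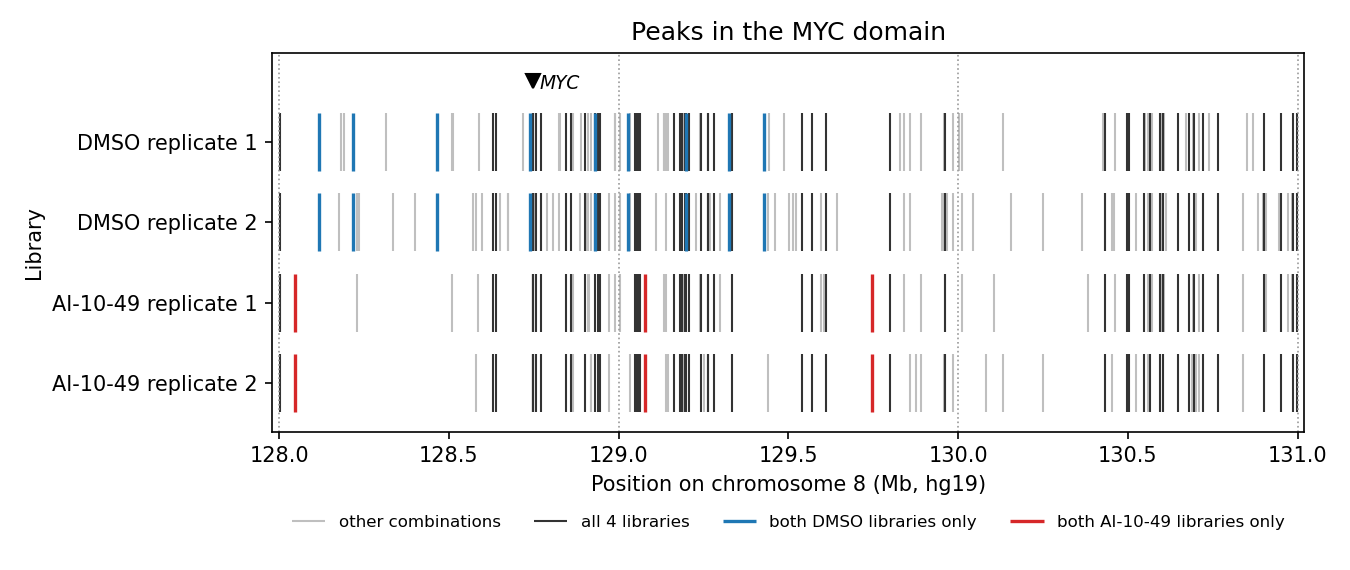
Each vertical tick is a peak, placed by position on chromosome 8 (horizontal axis, Mb, hg19) in the row of its library; colours mark regions of all 4 libraries, DMSO-only, AI-10-49-only and other regions, and dotted lines bound the bins. The 50 regions of all 4 libraries include the MYC peak, and the 9 DMSO-only regions lie in the first and the second bin.

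RUNX1 encodes the DNA-binding partner of CBFβ. Within 100 kb of the single approximate position used for it there were 22 regions, from chr21:36207845 to chr21:36399410. This window need not cover the whole gene and its flanks. Of these regions, 4 held a peak in all 4 libraries, 0 were DMSO-only and 2 were AI-10-49-only. The AI-10-49-only regions were chr21:36217014–36217126, with 5 and 8 reads, and chr21:36260419–36260530, with 13 and 6. CBFB, one partner gene of the inv(16) fusion, had 17 regions, of which 4 were found in all libraries, 1 was DMSO-only (chr16:67194043–67194134, 5 and 4 reads) and 2 were AI-10-49-only (chr16:67089707–67089861 with 6 and 6 reads, and chr16:67143706–67143868 with 6 and 7). AI-10-49-only regions were 2 of the 9 RUNX1 regions and 2 of the 8 CBFB regions found in both AI-10-49 libraries, against 5.36% elsewhere (two-sided Fisher's exact p = 0.0805 and 0.0648, adjusted p = 0.161 and 0.161 over 4 tests added after the data were seen). DMSO-only regions were 0 of 5 at RUNX1 and 1 of 5 at CBFB (Fisher's exact p = 1 and 0.467), and none of these tests passed the threshold.

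No 1 Mb bin of the genome passed the threshold for an excess of DMSO-only regions (0 of 2608) or of AI-10-49-only regions (0 of 2449), by Fisher's exact test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 117 and 68 bins, where regions placed at random would give 69.1 and 52.0 on average. Matching on strength left 75 and 66 at an unadjusted p under 0.05 and 0 and 0 after adjustment. For the matched test, the number of bins at random was not computed. The smallest p for DMSO-only regions, 0.000372 (adjusted 0.323), was shared by chr2:211000001–212000000, chr4:130000001–131000000 and chrX:149000001–150000000, each with 6 DMSO-only regions of 10. For AI-10-49-only regions the smallest was 0.000528 (adjusted 0.673) at chrX:153000001–154000000, with 8 of 36 regions, followed by chr20:61000001–62000000 with 7 of 28 and chr19:47000001–48000000 with 8 of 40. The next 9 bins for DMSO-only regions were chr5:106000001–107000000, chr9:72000001–73000000, chr5:111000001–112000000, chr11:97000001–98000000, chr14:41000001–42000000, chr12:71000001–72000000, chr4:127000001–128000000, chr13:81000001–82000000 and chr14:72000001–73000000. For AI-10-49-only regions they were chr17:2000001–3000000, chr1:9000001–10000000, chr19:16000001–17000000, chr20:57000001–58000000, chr17:79000001–80000000, chr19:49000001–50000000, chr19:13000001–14000000, chr22:31000001–32000000 and chr19:4000001–5000000. Of the 12 bins with the smallest p, 5 were on chromosome 19 for AI-10-49-only regions and 0 for DMSO-only regions. The 12 bins together held 79 AI-10-49-only regions of 371, and 63 DMSO-only regions of 114.

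Peaks after AI-10-49 lay more on gene-dense chromosomes, a comparison chosen after the data were seen. Chromosome 19, which has the most genes per Mb, held 3.30% and 3.03% of peaks in the DMSO libraries and 4.05% and 3.88% in the AI-10-49 libraries, a log2 ratio of 0.32. Chromosomes 22 and 17 followed with 0.23 and 0.21, and chromosomes 4 and X were lowest with -0.12 and -0.12. Over 23 chromosomes the log2 ratio rose with genes per Mb (Pearson's r = 0.848, permutation p = 1e-05, the smallest that these permutations can give, adjusted p = 3.4e-05 over 17 correlations; Spearman's rho = 0.798, p = 3e-05, adjusted p = 0.000255). Without the 2 chromosomes farthest from the median gene density r was 0.769, and chromosomes are not independent replicates. With all peaks, replicates differed in the same way but less. There r was 0.704 (permutation p = 0.00078) for DMSO replicate 1 over replicate 2 and 0.677 (p = 0.00026) for AI-10-49 replicate 1 over replicate 2. The slopes were 0.00971 and 0.00384 log2 units per gene per Mb, against 0.0220 between treatments. The relation between the AI-10-49 replicates was lost with the strongest 24465 peaks (r = 0.292, permutation p = 0.181) and with pileups of at least 60 times the background (r = 0.0497, permutation p = 0.84), where r between the DMSO replicates was 0.657 (p = 0.00041) and 0.673 (p = 0.00133). On chromosome 19, 5.71% of regions in both DMSO libraries were DMSO-only and 9.23% of regions in both AI-10-49 libraries were AI-10-49-only.

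**Figure D4:**
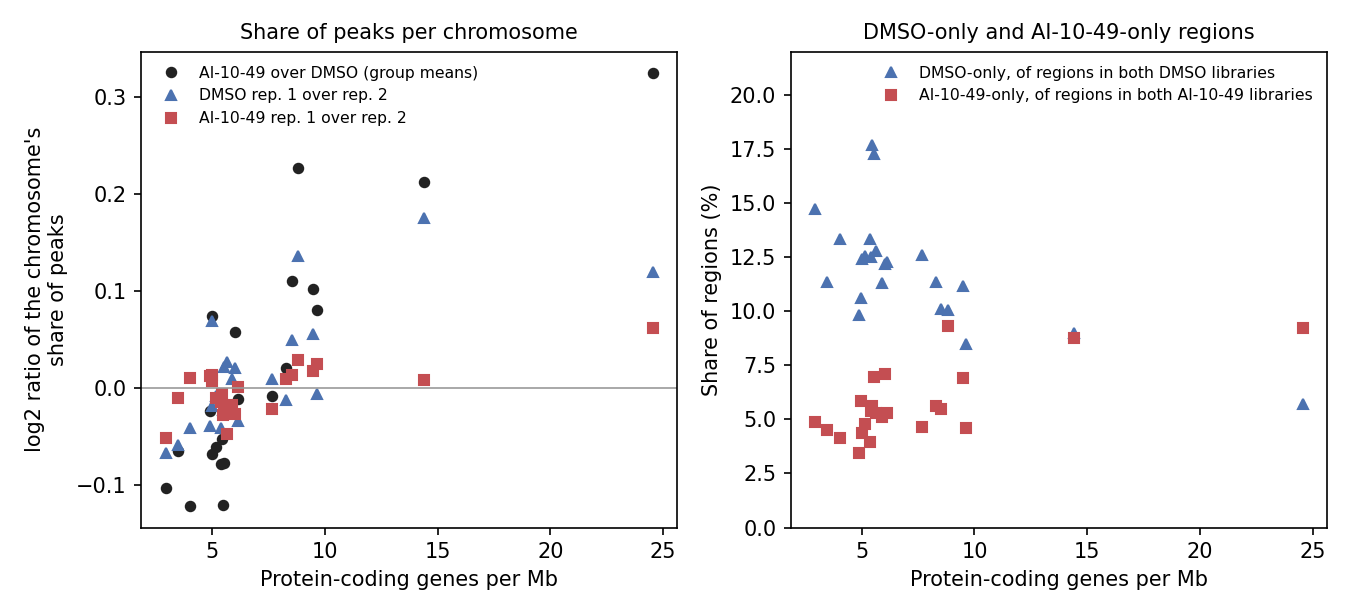
Left, log2 ratio of each chromosome's share of peaks (vertical axis) by protein-coding genes per Mb (horizontal axis) for the treatment groups and for the replicates of each group; right, the share of DMSO-only and AI-10-49-only regions in percent on the same horizontal axis. Each point is 1 of 23 chromosomes without an error bar, and chromosome 19 lies at the far right with a log2 ratio of 0.32 between treatments.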

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

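Settings with a pileup of at least 60 times the background or of at least 5 reads were chosen after the data were seen. The MYC domain kept its side of the threshold in all 11 alternatives, with odds ratios (for matching, ratios to the matched mean) of 0 to 1.36 and p of at least 0.108 for DMSO-only regions, and of 0.312 to 4.07 and p of at least 0.222 for AI-10-49-only regions. The share of DMSO-only regions changed direction with the setting, and counts of 4840 and 1985 changed with it. The regions themselves changed too. Of the 4840 DMSO-only regions, 2275 overlapped such a region with the strongest 48930 peaks and 153 with the strongest 24465. The number was 435 with a −log10 q-value of at least 5, 1349 at 60 times the background and 520 with at least 5 reads. Of the 1985 AI-10-49-only regions, the numbers were 1678, 125, 407, 497 and 1025 in the same order. With a −log10 q-value of at least 5 there were 1355 DMSO-only regions, a share of 35.7%, and AI-10-49 lists had 1940.5 more peaks and 561521 bp more covered length on average. With the strongest 48930 peaks there were 2489 and 3018 AI-10-49-only regions, 45.2%, and 5 bins with an excess of the latter. The strongest 24465 peaks gave 1311 DMSO-only regions and 44.6%. A percentile of at least 50 gave 519 and 147 regions and 77.9%, fewer by construction. Pileups of at least 60 times the background gave 689 AI-10-49-only regions, 88.4% and 2 bins. At least 5 reads gave 1025 and 3132 regions, 24.7%, and 5544 more peaks with AI-10-49 on average. Reciprocal overlap of 50% gave 3098 AI-10-49-only regions and 63.0%. Apart from the construction of the lists, the cause was not tested.

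Over regions, replicate numbers gave no sign of pairing: the correlation of deviations of same-numbered libraries was 0.00401. By chromosome, with all peaks, the log2 ratio of replicate 1 over replicate 2 rose with genes per Mb in both groups. Pearson's r was 0.704 with DMSO and 0.677 with AI-10-49. With pileups of at least 60 times the background r was 0.673 and 0.0497, and with the strongest 24465 peaks 0.657 and 0.292. Whether same-numbered libraries share a batch was thus not settled. A replicate block, the mean over same-numbered pairs, gave 27680.5 and 12803 regions and 68.4%, and cross-numbered pairs gave 27703.5, 12826 and 68.4%; these counts are higher because a region then needs a peak in 1 library and not in another. Leaving out each library gave 7611 to 22039 DMSO-only and 4391 to 8502 AI-10-49-only regions, also higher by construction, and shares of 47.2% (without AI-10-49 replicate 1) to 83.4% (without DMSO replicate 2). Bins with an excess numbered 0 to 4 for DMSO-only regions, with 4 without DMSO replicate 1 and 1 without DMSO replicate 2, and 0 to 1 for AI-10-49-only regions, with 1 without DMSO replicate 1 and 1 without AI-10-49 replicate 1. Mean overlap within groups minus that between groups ran from -0.0351 without AI-10-49 replicate 1 and -0.0232 without AI-10-49 replicate 2 to 0.0904 without DMSO replicate 1, against 0.0253 with all libraries. Promoter, gene list and motif tests, with their windows and their matching on GC content, and the 50 kb window of gene assignment were not run, because no annotation or sequence of hg19 was used here. Total reads per library are unknown, which limits every comparison of weak peaks.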

Other observations

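Tests at 60 times the background and at 5 reads, the simulated loss, the comparison of chromosomes and its test between replicates were chosen only after the results were seen. With the strongest 48930 peaks of every list, 5 bins passed the threshold for an excess of AI-10-49-only regions. They were chr19:47000001–48000000 with 13 of 39 regions (one-sided Fisher's exact test, adjusted p = 0.0272), chr22:50000001–51000000 with 11 of 32 (0.0323), chr22:23000001–24000000 with 9 of 22 (0.0323), chr9:132000001–133000000 with 7 of 14 (0.0352) and chr17:79000001–80000000 with 11 of 34 (0.0352), against 8.47% over the genome. The same test passed 0 bins in the deposited lists, and 0 with the strongest 24465 peaks. Of the 12 bins with the smallest p for AI-10-49-only regions in the deposited lists, chr19:47000001–48000000 and chr17:79000001–80000000 were among these 5.

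Few of the peaks with 2 reads recurred. In DMSO replicate 1, 19.1% of the 10239 such peaks overlapped a peak of DMSO replicate 2. At least 1 of the 2 AI-10-49 libraries had an overlapping peak for 16.7%, and a single AI-10-49 library for 10.9% on average. In DMSO replicate 2 the values were 18.2%, 16.4% and 10.9% of 10790 peaks. At 10 to 19 reads, 96.6% of DMSO replicate 1 peaks were found in DMSO replicate 2. Of the DMSO-only regions, 3491 (72.1%) had 2 or 3 reads in at least 1 DMSO library.

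DMSO-only regions outnumbered AI-10-49-only regions in the deposited lists, 4840 to 1985. A longer DMSO list stays open. With lists of equal length the share was 45.2% (95% interval 43.9 to 46.5%), below the bound of 60% set beforehand. A simulated loss of sites as weak as the DMSO-only regions also fell below it at equal length, from 73.2% to 53.6%. A loss at any strength went from 78.5% to 64.6%. The draws ended at 53.4 to 53.8% and at 64.1 to 64.8%. The simulation started from the lists of equal length, which already gave 45.2%, so it could hardly end lower. Ending above 45.2% therefore does not count against a loss, and the simulation shows only that passing the bound does not exclude one. A lower read minimum in the DMSO lists stays open. Pileups of at least 60 times the background raised the share to 88.4%, past the bound set against this explanation, but that bound was unsound, since the setting asked for 4 reads in the DMSO libraries and 6 or 7 in the AI-10-49 libraries, and at least 5 reads, which is a higher multiple of the background with DMSO (81.6 and 83.3) than with AI-10-49 (51.8 and 46.5), gave 24.7%. A treatment effect cannot be told apart from depth. At equal length the DMSO pair alone held 1.18 times as many regions as the highest mixed pair (2489 against 2107), and the AI-10-49 pair held 3018. The DMSO pair also held more with pileups of at least 60 times the background (5237 against 1548). It held fewer with a −log10 q-value of at least 5 (1355 against 2089) and with at least 5 reads (1025 against 2075). Both AI-10-49 libraries also had a higher background than both DMSO libraries.

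The shift of peaks toward gene-dense chromosomes after AI-10-49 was not limited to weak peaks. With the strongest 24465 peaks of every list the slope was 0.945 times that with all peaks, which argues against weak DMSO peaks as its cause. The relation was looser at this setting, with r between treatments of 0.669 against 0.848 with all peaks. Without the 2 chromosomes farthest from the median gene density it was 0.513 against 0.769. A library difference that also separates replicates stays open. With all peaks the larger slope between replicates was 0.442 times the slope between treatments, between the bounds of 0.5 and 0.25 set for this test. It was 0.597 times with the strongest 24465 peaks, past the upper bound, and 0.440 times with pileups of at least 60 times the background. Those values are from the DMSO replicates. For the AI-10-49 replicates they were 0.175, 0.107 and 0.0112, all under the lower bound. That bound counts against the explanation only if both groups lie under it, and the DMSO replicates did not. A treatment effect on gene-dense chromatin may also contribute, as a hypothesis that 2 libraries per group cannot separate from library quality. GC content was not tested, as no sequence of hg19 was used here.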
